A study of Drosophila melanogaster with 4 samples.

How the data were processed

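Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was performed for H3K36me3, histone H3 trimethylated at lysine 36, in wild-type Oregon-R embryos of Drosophila melanogaster aged 14 to 16 h. Oregon-R is a standard wild-type laboratory strain. Per the labels' protocols, embryos were dechorionated with bleach and crosslinked with 1.8% formaldehyde, and antibody-bound chromatin was collected on beads, washed, treated with RNase A and proteinase K, and freed of crosslinks. The labels list 4 libraries, which are 2 H3K36me3 ChIP libraries and 2 input libraries. Each input library is named in its description as the input of 1 of the ChIP region lists. The labels do not say whether the replicates came from separate embryo collections, so the spread between them may be technical.

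The submitters' processing notes name Bowtie 0.12.7. The program that called the regions, its threshold and its filters are not given in the sources used here. Per the file headers, coordinates refer to FlyBase release 5. Each file is a list of enriched regions with a start, an end and a score, and the score is the authors' deposited score, whose scale and unit are not stated. There is 1 list for each ChIP replicate and 1 list for the whole series, called the series-level set here. How that set was made from the replicates is not given in the sources used here. The files hold called regions and no read counts, so the sequencing depth is unknown, and no region outside the lists has a value. The input libraries enter only through the authors' calls and were not analysed here on their own.

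The scale of the deposited score was tested on tied scores, since scores computed from small whole numbers should repeat. Differences between distinct tied scores were raised to a base, and the result was called a ratio of small whole numbers when it lay within a relative tolerance of 1e-09 of a fraction with a denominator of at most 100. With base 2 this held for 299 of 1326 pairs in replicate 1, 2155 of 14196 pairs in replicate 2 and 456 of 1431 pairs in the series-level set. With base e it held for 0 pairs in each list, and with base 10 for 2, 10 and 5 pairs. Scores were therefore read as base-2 logarithms of a ratio up to an unknown constant. They are used to describe and rank regions within a list, and since the constant may differ between lists, score levels given for both replicates are not compared between them. The correlation of paired regions does not depend on the constant.

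Regions were read with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. In each list 1 region at the end of 3L ran past the sequence length of 24543557 given in the file headers, by 922 bases in replicate 1, 823 in replicate 2 and 1007 in the series-level set, and these bases were left out. Covered share means the percent of a sequence's length, as given in the headers, that lies in regions. Main arms are 2L, 2R, 3L, 3R, 4 and X. Heterochromatin scaffolds are 2LHet, 2RHet, 3LHet, 3RHet, XHet and YHet. U and Uextra hold sequence not placed on a chromosome.

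The overlap of the replicates was measured as the share of bases covered in either replicate that were covered in both. It was compared with 10000 circular shifts of the replicate 2 regions along each sequence, which keep the widths and spacing of the regions, by a one-sided permutation test. A region was shared when at least 1 base overlapped the other replicate. Shares of regions have 95% Wilson intervals, which cover counting error only and treat regions as independent. Medians were compared by two-sided permutation tests with 100000 resamples, with Benjamini-Hochberg adjustment over the 4 tests on shared and unshared regions and over the 8 tests per list on chromosome classes. The smallest p these tests can give is 1e-05, and 0.0001 for the shifts. Regions are not independent replicates, so these p-values describe each library. With 2 replicates no test across replicates was made, and values are given as mean ± SD (n = 2). The shift test was checked on simulated regions with the widths of the 699 regions of 2L in replicate 1. It called 2 of 40 unrelated pairs of sets below 0.05 and 40 of 40 pairs that shared most regions. The simulated regions were placed at random on 2L, so the check does not cover region sets that cluster along a sequence. The test of medians called 4 of 40 simulated sets of 600 values without a difference.

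The named regions were fixed before the data were examined. They are the 5 longest replicate 1 regions that overlapped a replicate 2 region by 50% of both lengths, the 5 longest unshared regions per replicate and the 5 highest-scored regions per replicate. The alternatives fixed before the data were examined were the higher-scored 50% of regions, main arms only, merging of regions within 1 kb, an overlap of 50% of both lengths, and leaving out each replicate. The ratio of chromosome 4 to the autosomal arms, the comparison of X with autosomes in 1 Mb blocks, the tests on widths and scores by chromosome class, the counts of highest scores on chromosome 4 and U, the pairs of matching regions, the test between arms, the centromere-proximal comparison and the list of gaps were added after the data were seen. Planned tests on genes, exons and fixed gene lists were not run. The gene table at hand belongs to Release 6, and its coordinates cannot be set beside release 5 regions, so regions are given by position and no gene is named.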

Results

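Regions enriched for H3K36me3, a histone mark found over the bodies of transcribed genes, were mapped in 14 to 16 h Oregon-R embryos, a late stage of embryonic development. Both ChIP replicates gave similar lists. Replicate 1 held 4238 regions covering 23.6 Mb, and replicate 2 held 4320 regions covering 21.8 Mb. The replicates averaged 4279 ± 58.0 regions (SD, n = 2) and covered 18.5% ± 0.979 of the main chromosome arms (SD, n = 2). Regions were kilobases wide, with a median of 4530 bp in replicate 1 and 4189 bp in replicate 2. The middle 50% of widths ran from 3060 to 7058 bp in replicate 1 and from 2872 to 6292 bp in replicate 2. The median deposited score was 1.55 in replicate 1 and 1.56 in replicate 2. The files hold no read counts, so the depth behind each region is unknown, and sequence outside the regions has no value.

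The first comparison asked whether the 2 libraries marked the same parts of the genome. Together the replicates covered 23.9 Mb, of which 21.5 Mb, or 90.1%, was covered in both. Circularly shifted regions shared 10.3% on average and 19.1% at most, so the observed overlap lay above each of the 10000 shifts (one-sided permutation p = 0.0001, the smallest the shifts can give). Replicate 2 lay almost wholly inside replicate 1, with 98.8% of its bases there, whereas 91.1% of replicate 1 bases lay in replicate 2. Of the replicate 1 regions, 3916 of 4238 (92.4%, 95% Wilson interval 91.6 to 93.2) overlapped a replicate 2 region, against 29.2% on average under shifts. Of the replicate 2 regions, 4268 of 4320 (98.8%, interval 98.4 to 99.1) overlapped a replicate 1 region, against 30.1% under shifts. With an overlap of 50% of both lengths, the shares were 89.9% and 88.1%.

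The longest regions that matched in both replicates were domains of more than 20 kb in replicate 1. They lay on 2R from 4771905 to 4800567 (28663 bp, score 1.89), on 2R from 9742257 to 9770456 (28200 bp, score 1.74), on 3L from 2766697 to 2794588 (27892 bp, score 1.72), on X from 15607871 to 15632863 (24993 bp, score 2.29) and on 3R from 17840953 to 17865390 (24438 bp, score 2.12). The matching replicate 2 regions were 22877, 17543, 19740, 23384 and 19128 bp wide, with scores of 1.69, 1.83, 1.54, 2.19 and 2.13. The widest region of either replicate, chosen after its values were seen, lay on X from 1750885 to 1791523 (40639 bp). Replicate 2 split it into 3 regions that together covered 98.0% of it. In all, 352 replicate 1 regions overlapped more than 1 replicate 2 region, while 33 replicate 2 regions overlapped more than 1 replicate 1 region.

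Where 1 region matched exactly 1 region of the other replicate, which gave 3525 pairs, the replicate 1 region was wider in 3079 pairs (87.3%). The median difference was 220 bp, from medians of 4533 and 4231 bp, and the sign-flip permutation p was 1e-05, the smallest it can give. The edges moved outward on both sides, with replicate 1 regions starting a median of 100 bp earlier and ending a median of 99 bp later. Scores of the paired regions ranked alike across regions (Pearson r = 0.956, Spearman rho = 0.956, permutation p = 1e-05 for each). These correlations are across regions of 2 libraries, and regions are not independent replicates.

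The second comparison asked how the mark was spread over the chromosomes. Chromosome 4, the small dot chromosome that carries active genes in a largely heterochromatic setting, was covered most. Regions took up 42.5% ± 1.19 of its 1.35 Mb (SD, n = 2), against 18.3% ± 0.945 of the autosomal arms 2L, 2R, 3L and 3R, a ratio of 2.33 ± 0.0553 (SD, n = 2). The difference exceeded the spread between replicates many times over, with 43.4% and 41.7% on chromosome 4 and 18.9% and 17.6% on the autosomal arms in replicates 1 and 2. No stretch of 2L, 2R, 3L, 3R or X as long as chromosome 4 reached its level. Among 11230 such windows per replicate, taken every 10 kb and so largely overlapping, the highest was covered to 37.5% in replicate 1 and 34.9% in replicate 2.

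**Figure D1:**
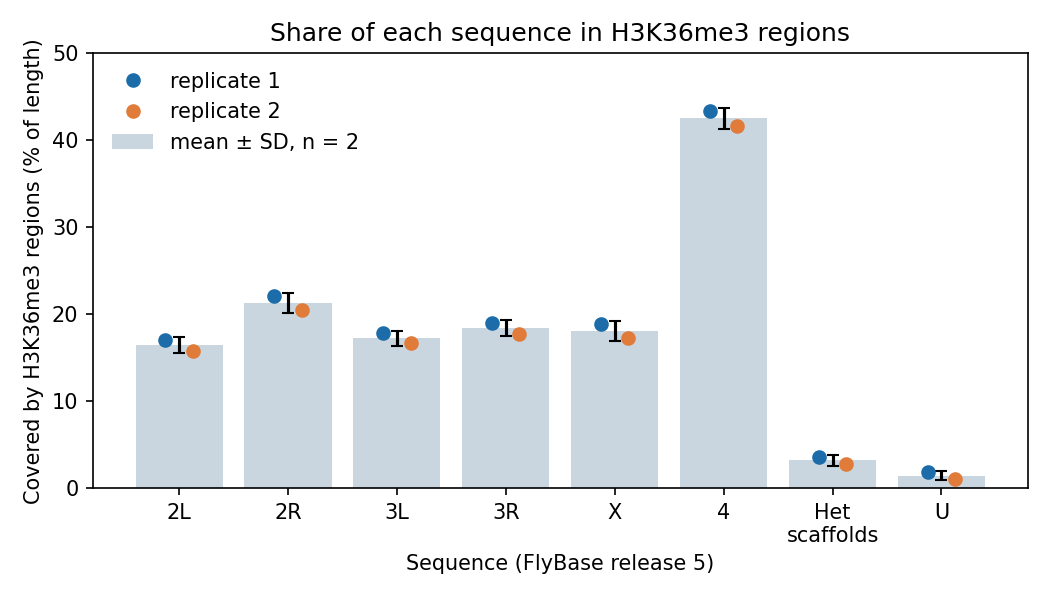
Covered share of each sequence, in percent of its length, for both H3K36me3 ChIP replicates. Bars are means, error bars SD (n = 2) and points the replicates; chromosome 4 stands at 42.5%, the large arms between 16.4% and 21.3%, and the 6 heterochromatin (Het) scaffolds, pooled into 1 bar, and the unplaced sequence U below 4%.

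Regions on chromosome 4 were also denser and wider. There were 57.7 and 62.9 regions per Mb in replicates 1 and 2, against 33.3 and 34.3 on the autosomal arms. Their median width was 6958 bp against 4622 bp on the large arms in replicate 1 (permutation, adjusted p = 3e-05) and 5110 bp against 4243 bp in replicate 2 (permutation, adjusted p = 0.0333). The median score on chromosome 4 differed from that on the large arms by -0.0665 in replicate 1 and -0.0186 in replicate 2, and neither difference passed the test (permutation, adjusted p = 0.499 and 0.876). The scores were spread more widely there, with upper quartiles of 2.49 and 2.53 against 1.88 and 1.85, and lower quartiles of 0.790 and 0.841 against 1.05 and 1.13.

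Chromosome 4 was over-represented among the highest scores. Of the 100 highest-scored regions, 23 in replicate 1 and 26 in replicate 2 lay there, although the chromosome held 1.84% and 1.97% of the regions (Fisher's exact test, two-sided, p = 3.3e-20 and 1.7e-23). The unplaced sequence U was over-represented too, with 5 and 6 of the 100 highest against 1.65% and 0.995% of the regions (Fisher's exact test, two-sided, p = 0.024 and 0.0004), and with 17 against 3.27% in the series-level set (p = 1.4e-08). These counts were chosen after the data were seen, so their p-values describe a pattern found in the same scores. Width and score were correlated over each list, so the larger widths and the high scores on chromosome 4 are not separate findings. Both replicates had their leading placed regions at the same positions. These ran from 668059 to 680139 (score 3.03 in replicate 1 and 3.14 in replicate 2), from 873536 to 887615 (3.01 and 3.11) and from 1133692 to 1143710 (2.96 and 3.10), by replicate 1 coordinates. The next on chromosome 4 were 1029169 to 1042303 in replicate 1 (score 2.90), and 328375 to 334913 (3.05) and 215862 to 226360 (3.01) in replicate 2. The top score of replicate 1, 3.54, belonged to an unplaced U region from 2027328 to 2029040 that no replicate 2 region overlapped.

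**Figure D2:**
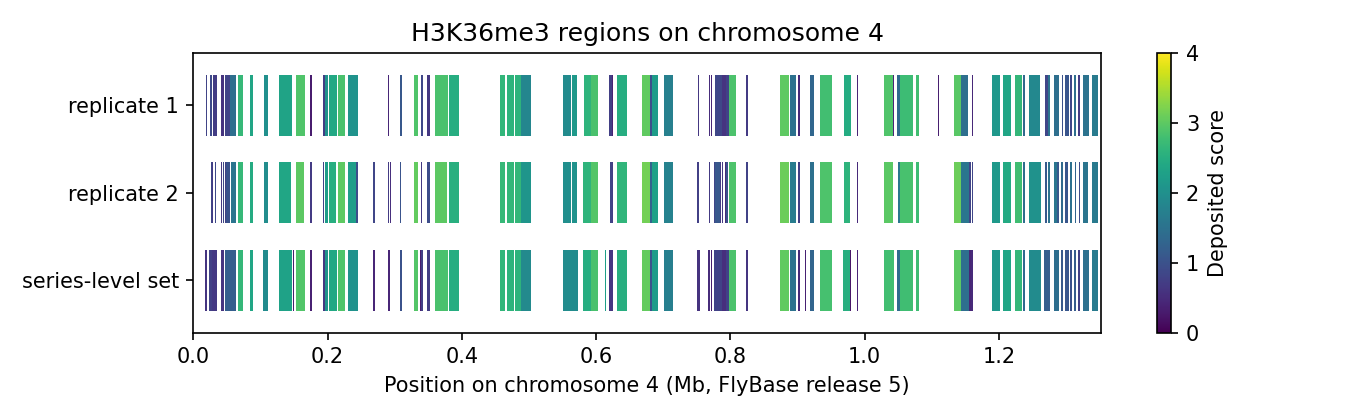
Map of chromosome 4 (position in Mb, FlyBase release 5) with the regions of each replicate and of the series-level set, drawn to scale and coloured by deposited score. High-scored and low-scored regions mostly lie at similar positions in the 3 lists. An exception is the series-level region from 612774 to 614632 (score 2.25), which no replicate region overlaps. The longest gap between regions of either replicate is 60.1 kb.

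The X chromosome, which is dosage compensated in males, had a covered share close to that of the autosomal arms. The lists do not separate male from female embryos, and covered share does not measure the level of the mark, so dosage compensation was not tested. X was covered to 18.1% ± 1.11 (SD, n = 2), a ratio to the autosomal arms of 0.990 ± 0.00968 (SD, n = 2). In 1 Mb blocks, 22 blocks of X averaged 18.4% and 95 autosomal blocks 18.4%. The difference was 0.0481 percentage points with a 95% bootstrap interval from -2.71 to 2.87 (two-sided permutation p = 0.974), and its sign differed between replicates (0.186 in replicate 1 and -0.0898 in replicate 2). Median scores of X regions were 1.59 and 1.57, against 1.57 on autosomal arms in both replicates, and neither scores (adjusted p = 0.499 and 0.905) nor widths (adjusted p = 0.875 and 0.529) passed the permutation test.

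Among the large arms, 2R was covered most, at 21.3% ± 1.13, followed by 3R at 18.4% ± 0.905, X, 3L at 17.2% ± 0.861 and 2L at 16.4% ± 0.915 (SD, n = 2 each). The order was the same in both replicates. Blocks of 1 Mb varied far more within arms than between them, from 4.52% to 32.7%, and arm accounted for 6.56% of the variance over 117 blocks (permutation p = 0.106). Replicate 1 was higher than replicate 2 in 117 of 117 blocks, by 1.38 percentage points on average (SD over blocks 0.556).

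**Figure D3:**
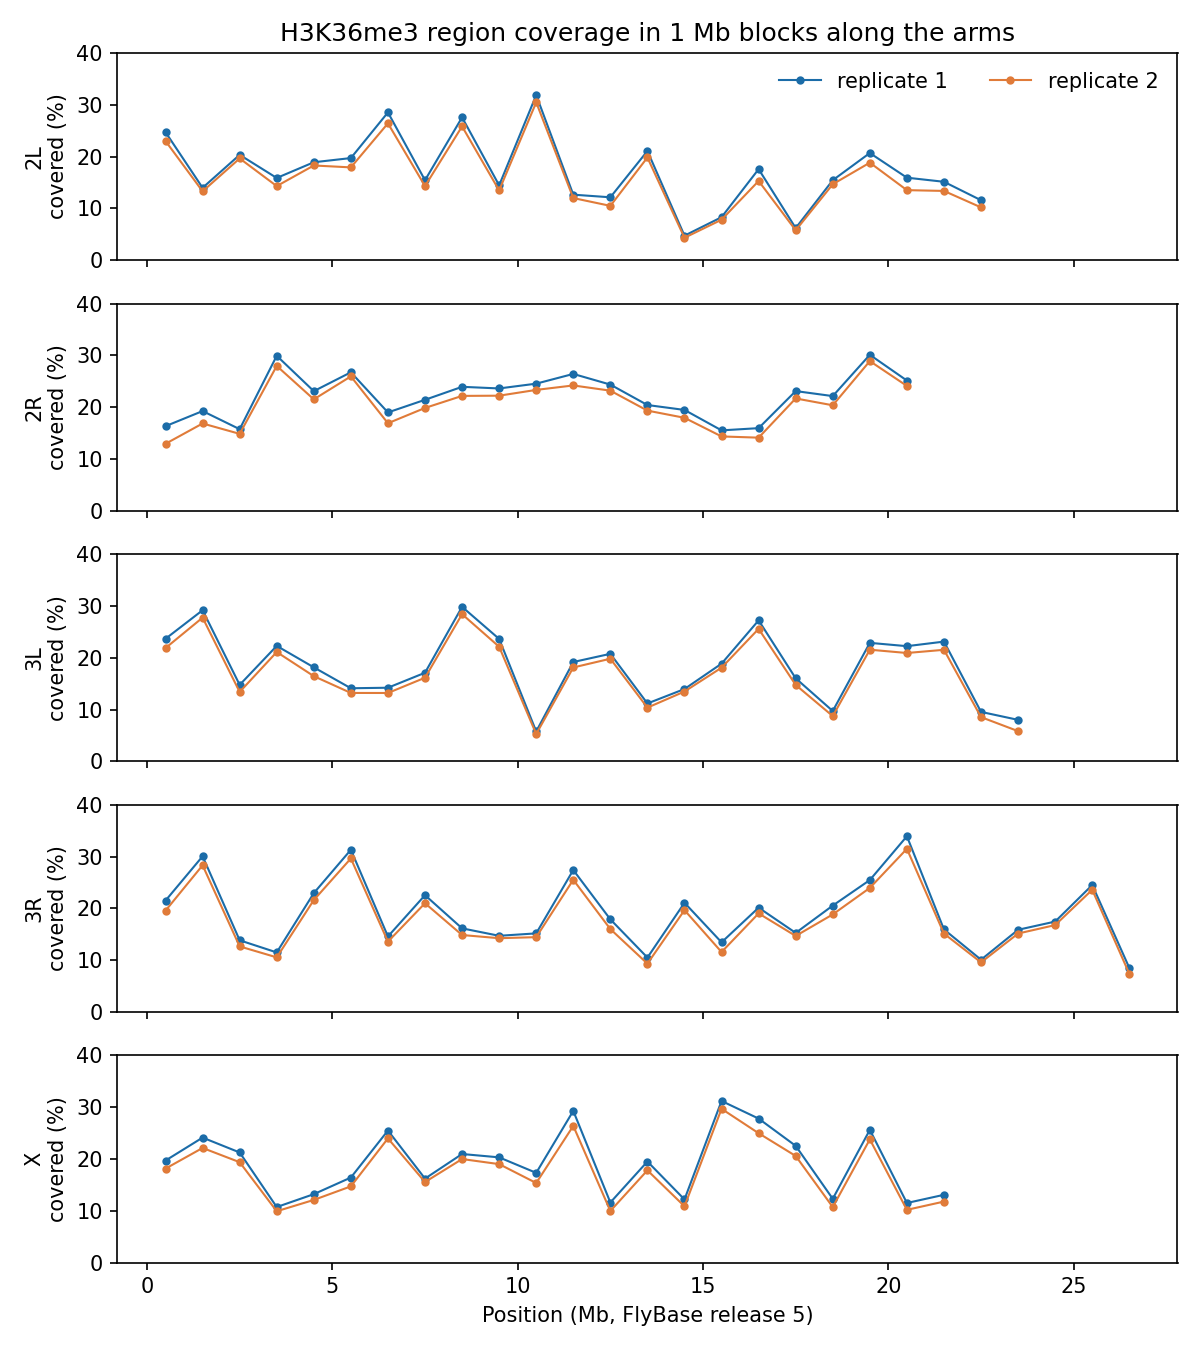
Covered share in whole 1 Mb blocks along the 5 large arms (position in Mb, FlyBase release 5; coverage in percent), with 1 line per replicate. Both replicates rise and fall together along each arm, between 4.52% and 32.7% as the mean of both, and replicate 1 lies above replicate 2 in each block.

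Pericentromeric and unplaced sequence carried few regions. The heterochromatin scaffolds, which hold pericentromeric and Y-linked sequence, were covered to 3.65% in replicate 1 and 2.76% in replicate 2 (SD 0.630, n = 2), or 0.175 ± 0.0255 times the autosomal arms. Single scaffolds ranged from 1.54% ± 0.336 on 3RHet to 9.59% ± 0.636 on XHet (SD, n = 2). The XHet value rests on 3 and 4 regions in replicates 1 and 2, on a scaffold of 0.204 Mb. U was covered to 1.46% ± 0.513 (SD, n = 2), and no list held a region on Uextra. Covered shares divide by the full sequence length. How much of these sequences reads could be placed on is unknown here, so few regions need not mean that the mark was absent. Regions on the heterochromatin scaffolds had lower scores than those on the large arms, with medians of 0.853 against 1.57 in replicate 1 and 1.03 against 1.57 in replicate 2 (permutation, adjusted p = 3e-05 and 8e-05). They were also narrower, with medians of 2868 against 4622 bp and 2634 against 4243 bp (permutation, adjusted p = 6e-05 and 0.0001). Since width and score were correlated over each list (Spearman rho = 0.711 and 0.725), the lower scores and smaller widths are not separate findings. Regions on U were narrower in both replicates, at 2293 and 2050 bp (permutation, adjusted p = 3e-05 and 0.0001). Their scores were lower in replicate 1, with a median of 1.33 (adjusted p = 0.0228), while the replicate 2 median of 1.42 did not pass the permutation test (adjusted p = 0.202).

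The third comparison asked which regions differed between the replicates. Regions found in 1 replicate alone were narrow and low-scored. The 322 unshared regions of replicate 1 had a median width of 1811 bp and a median score of 0.543, against 4838 bp and 1.61 for shared regions. The 52 unshared regions of replicate 2 had medians of 1589 bp and 0.744, against 4224 bp and 1.57. All 4 differences had an adjusted p of 1e-05 (permutation), the smallest the test can give. Width and score rose together in each list (Spearman rho = 0.711 in replicate 1 and 0.725 in replicate 2), so these tests are not separate evidence. A narrow region also has less room to meet the 1-base overlap that defines sharing. Counting as shared only an overlap of 50% of both lengths reduced the replicate 2 differences from -2634.5 to -1411.5 bp in width and from -0.825 to -0.411 in score. In replicate 1, 6.44% of regions on the main arms were unshared, against 29 of 100 on heterochromatin scaffolds and 31 of 70 on U. In replicate 2 the counts were 43 of 4197, 5 of 80 and 4 of 43.

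The longest unshared regions of replicate 1 lay on 2L from 12125642 to 12129897 (4256 bp, score 0.788), on 3LHet from 2445412 to 2449533 (4122 bp, 0.771), on 2L from 5032392 to 5036381 (3990 bp, 0.748), on 2L from 6765048 to 6768987 (3940 bp, 0.609) and on 2R from 16708898 to 16712789 (3892 bp, 0.651). Those of replicate 2 lay on chromosome 4 from 268059 to 270886 (2828 bp, score 0.841), on 3R from 16686046 to 16688765 (2720 bp, 0.819), on X from 2415971 to 2418343 (2373 bp, 0.786), on 2R from 19888599 to 19890780 (2182 bp, 0.896) and on chromosome 4 from 1155756 to 1157895 (2140 bp, 0.803).

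**Figure D4:**
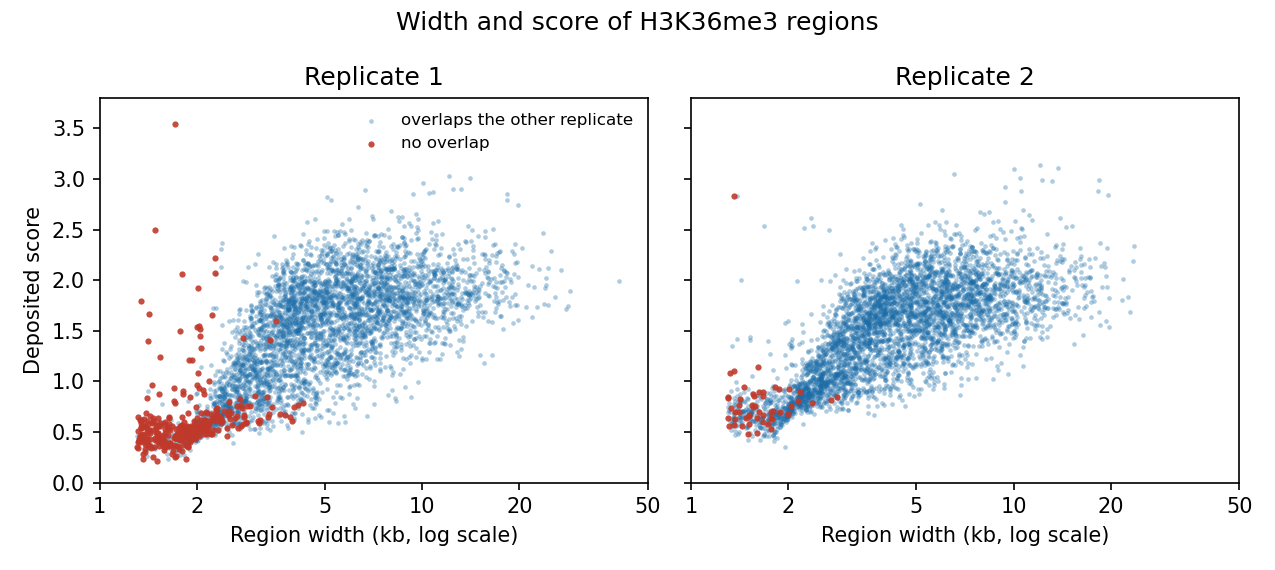
Width (kb, log scale) against deposited score of each region in both replicates, with regions that overlap the other replicate in blue and those that do not in red. Unshared regions gather at the narrow, low-scored end, with median scores of 0.543 in replicate 1 and 0.744 in replicate 2, and a few narrow unshared regions of replicate 1 have scores above 1.5.

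The series-level set held 4468 regions covering 24.7 Mb, more than either replicate. Of its bases, 87.3% lay in both replicates, 8.22% in replicate 1 alone, 0.934% in replicate 2 alone and 3.58% in neither. It overlapped all but 4 regions of replicate 1 and all but 3 of replicate 2. Of its regions, 3818 overlapped both replicates, with a median score of 1.57, and 302 overlapped neither, with a median score of 0.440. Chromosome 4 was covered to 46.1% in this set, the autosomal arms and X to 19.6% each, and the heterochromatin scaffolds to 4.89%. U held 146 series-level regions, against 70 in replicate 1 and 43 in replicate 2.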

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

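Across 25 results and 90 alternative settings, 62 settings kept the direction and side of the threshold or moved the value by less than its error, 25 moved a value beyond it, 1 lost a call and 2 turned a sign. Leaving out 1 of 2 replicates always moves their mean by less than their SD. For coverage and the chromosome 4 ratio, those settings could therefore not have counted as moved, and they say nothing about stability. The overlap of the replicates stayed above the shifts (permutation p = 0.0001) at 82.7% with the higher-scored 50% of regions, 90.8% on main arms only and 90.6% with regions within 1 kb merged. Unshared regions stayed narrower and lower-scored in each alternative run, but with an overlap of 50% of both lengths the replicate 2 differences shrank from -2634.5 to -1411.5 bp and from -0.825 to -0.411 in score. The share of replicate 1 regions that were shared was 91.0% with the higher-scored 50%, 93.6% on main arms only and 89.9% with an overlap of 50% of both lengths; for replicate 2 it was 93.5% with the higher-scored 50% and 88.1% with an overlap of 50% of both lengths. The share of series-level bases in both replicates was 80.9% with the higher-scored 50%, 88.6% on main arms only and 87.7% with merging. Each list was cut at its own median score, so a region could lose its partner to the cut. The lower overlap and shares with the higher-scored 50% therefore do not show that higher-scored regions matched less well. Keeping the higher-scored 50% lowers coverage by construction, to 10.9% on 2L, 14.2% on 2R, 11.4% on 3L, 12.6% on 3R, 11.9% on X, 31.9% on chromosome 4, 0.630% on heterochromatin scaffolds and 0.624% on U, and the ratio of chromosome 4 to the autosomal arms was then 2.62. In the series-level set, added after the data were seen, coverage was 17.7%, 22.9%, 18.5%, 19.6%, 19.6%, 46.1%, 4.89% and 3.03% in the same order. Without 1 replicate the ratio for chromosome 4 ranged from 2.29 to 2.37, and its share of the 100 highest scores from 23 to 26%; with the 50 and 200 highest that share was 44% and 13.3%. The difference of X from the autosomes, which passed no test, was -0.248 points with the higher-scored 50% (permutation p = 0.825) and ranged from -0.0898 to 0.186 when either replicate was left out. These values all lie within the bootstrap interval of the main difference, from -2.71 to 2.87. That interval covers the spread between blocks and not the effect of a setting. Since it holds both signs, no direction can be read from the sign changes, whose cause was not tested. The lower score of U regions in replicate 1 was -0.152 in replicate 2 and did not pass there. No paired analysis was possible because the numbers shared by ChIP and input libraries only tie each input to its ChIP region list, and the inputs have no values of their own here. Alternatives set out for the tests on genes were not run. With no read counts, weak enrichment outside the regions cannot be told from none.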

Other observations

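All tests in this part were chosen after the data were seen, those on chromosome 4 after its coverage was known but before their own results were. Long stretches of the large arms carried no region in either replicate. There were 251 gaps of 100 kb or more between regions, adding up to 45.2 Mb, or 37.6% of the main arms. They took up 45.6% of 2L, 44.0% of X, 36.7% of 3L, 35.9% of 3R and 27.6% of 2R, and chromosome 4 had 0 such gaps. The longest lay on 2R from 15562259 to 16128400 (566.1 kb), on 2L from 14493929 to 15005308 (511.4 kb), on X from 20396279 to 20896038 (499.8 kb), on 2L from 16918268 to 17367041 (448.8 kb) and on 3L from 18163460 to 18611256 (447.8 kb). Each of the 3 longest held 1 region of the series-level set, and the other 2 held 0.

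The richest 1 Mb blocks of the large arms began at 20000001 on 3R (33.9% and 31.5% in replicates 1 and 2), at 10000001 on 2L (31.9% and 30.5%) and at 5000001 on 3R (31.3% and 29.6%). The poorest began at 14000001 on 2L (4.72% and 4.32%) and at 10000001 on 3L (5.77% and 5.28%), which lie away from the ends of the arms. Next came the block at 17000001 on 2L (6.19% and 5.76%). It was followed by those at 23000001 on 3L (8.01% and 5.83%) and 26000001 on 3R (8.51% and 7.38%), the last whole blocks of their arms. That end is centromere-proximal on 3L, but on 3R it is the end away from the centromere. Coverage of the centromere-proximal 1 Mb of the assembled arm, which leaves out the heterochromatin scaffolds, was below the rest of the arm on 4 of 5 arms. It was 3.45% ± 0.798 against 17.8% ± 0.864 on 3L, 6.82% ± 0.551 against 18.6% ± 1.14 on X, 10.9% ± 0.978 against 16.7% ± 0.912 on 2L and 14.6% ± 2.41 against 21.6% ± 1.07 on 2R (SD, n = 2). On 3R it was higher, at 20.5% ± 1.37 against 18.3% ± 0.888 (SD, n = 2). Over the 5 arms the mean difference of -7.34 percentage points did not pass an exact sign-flip test (two-sided p = 0.125, where 0.0625 is the smallest that 5 arms allow).

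Chromosome 4 was covered 2.33 times as much as the autosomal arms. If this came from many weak regions, the higher-scored 50% of regions should bring the ratio below 1.5, but it was 2.45 in replicate 1 and 2.79 in replicate 2 (mean 2.62 ± 0.238, SD, n = 2), which argues against that explanation. If poorly covered sequence near the centromeres accounted for the lower mean of the arms, some arm windows as long as chromosome 4 should reach its level. Of the 11230 windows per replicate, 0 did, though neighbouring windows overlap and are not independent. This does not measure how far such sequence lowers the mean. Without their centromere-proximal 1 Mb, the large arms were covered to between 16.7% (2L) and 21.6% (2R), against 42.5% on chromosome 4. These values argue against that 1 Mb accounting for the difference. Gene density, repeat content and copy number of the chromosome stay open, since they need an annotation and reads, and no biological explanation was tested.

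Replicate 1 covered 1.82 Mb more than replicate 2, an excess of 8.36%, and 70.3% of the bases found in replicate 1 alone lay in regions that both replicates shared. Leaving out replicate 1 regions below the lowest replicate 2 score of 0.350 left 97.1% of the excess, but this removed only 33 of 4238 regions, cannot trim the edges of shared ones, and sets scores of lists whose constants may differ side by side, so a looser limit in replicate 1 stays open. Fewer reads in replicate 2 are a candidate explanation. Tied scores, which small whole-number counts produce, were 3.50 times as frequent there (393 of 4320 regions against 110 of 4238), and on main arms they made up 8.10% in replicate 2, 1.89% in replicate 1 and 1.56% in the series-level set. Which counts entered the score is unknown, so the ties cannot tell few ChIP reads from few input reads. Differences in fragment length, antibody performance or embryo collection stay open.

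The series-level set held 146 regions on U, of which 74 overlapped neither replicate. Of these, 43 (58.1%) were narrower than 1301 bp, the narrowest region of either replicate, so a smaller minimum width in the series-level list may account for that part. Weak regions gained by combining replicates could not be decided for U, since the median score differed from that of the other series-level regions by -0.0977 (1.37 against 1.47, permutation p = 0.354). Narrow regions were not particular to U. On the main arms, 84 of the 181 series-level regions without a partner were narrower than any replicate region, and the 181 had a median score of 0.383. Placement of reads in repeated sequence stays open, as it needs the reads.

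All 4468 series-level regions started and ended at even positions, whereas 2111 of 4238 starts in replicate 1 and 2172 of 4320 in replicate 2 were even. The 5 highest series-level scores, from 3.25 to 4.25, belonged to U regions 1003 to 1899 bp wide that no replicate 1 region overlapped.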
